A study of Mus musculus with 12 samples.

How the data were processed

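Microglia of C57BL/6J mice were profiled on 12 Affymetrix Mouse Gene 1.0 ST arrays. Per the labels, cells taken on postnatal day 7 were cultured for 3 days and then given Aβ42 at 10 µM or its DMSO vehicle at 0.4%, with AE1-329 at 100 nM or its ethanol vehicle at 0.001%, for 6 h. This gave 4 groups of 3 arrays. Group and replicate number of each array were taken from the labels, and no value column remained without a sample. The submitters' design text states that 3 litters were the biological replicates of each treatment.

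The deposited values are log2 expression values, 1 per probe set and array. RMA, which usually means background correction, quantile normalization and a summary of probes, and Partek 6.5 are named per the submitters' processing notes, without their role. The log2 scale was read from the values, which ran from 2.79 to 13.95 with array medians between 6.97 and 7.05. Filters, any correction for litter and the genome build are not given in the sources used here. RMA in that form aligns arrays at the level of probes, and changes are then relative to the bulk of genes. Scanner files and background signals were not used here, so the signal over background of single probe sets is unknown, and the number of arrays limits the precision.

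Of 35556 probe sets, 21789 carried 1 gene symbol in the platform annotation, 1621 carried several and 12146 none. Gene IDs of 21698 of the first kind were matched in the RefSeq table of mouse assembly GRCm38.p6, which served for names only, and the others kept the annotation's symbol. Genes were named only from probe sets with 1 symbol, and where a gene had several, which held for 999 genes, the probe set with the highest mean over the 12 arrays was kept. This left 19938 genes, with no filter on dim ones. Another probe set of the same gene had the opposite call for Camta1 and Taf1d with Aβ42 alone and for no gene in the other comparisons.

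Group means were fitted to all 12 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 8 residual degrees of freedom, 4.54 prior degrees of freedom), because 3 arrays per group leave few degrees of freedom for a fit to 2 groups. All p-values are two-sided, and p was adjusted by Benjamini-Hochberg within each comparison with a threshold of 0.05. The comparisons were Aβ42 alone against vehicle, Aβ42 with AE1-329 against Aβ42 alone, AE1-329 alone against vehicle, Aβ42 with AE1-329 against AE1-329 alone, and the interaction. A change of 2-fold is 1 log2 unit. Fixed gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 29 lists with at least 5 measured members, and again with a correlation estimated from the data and with fry, which tests whether the genes of a list move one way on balance. Counts given as adjusted over the list alone used Benjamini-Hochberg over the members of that list. A list's share of the Aβ42 response was the ratio of its mean changes within a litter.

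Designs, alternatives, the 30 gene lists and the rule for named genes were written before the data were examined. The rule took, per comparison, up to 10 genes with the highest and up to 10 with the lowest change among those that passed and whose groups did not overlap (for the interaction up to 5 each way, overlap allowed), in each list the 4 members with the smallest p, and in every comparison Ptger4, Ptger2, Tnf, Il1b, Il6, Il10, Ccl2, Nos2, Irf1, Irf7, Cybb and Ptgs2. The text names a part of the list members so chosen. Predicted genes, olfactory receptors and microRNA genes were counted but not named. The list of sex-linked genes, with 4 measured members, was too short for camera. None of its members passed limma's test in any comparison, with 1 at an unadjusted p under 0.05 for Aβ42 alone against vehicle and 0 in the others. With the replicate block 3 of the 4 passed as lower for Aβ42 alone, namely Kdm5d (-0.25, adjusted p = 0.0309), Uty (-0.31, 0.0199) and Xist (-0.24, 0.0240), and 0 in the others. Kdm5d and Uty also passed without vehicle replicate 2 (0.0257 and 0.0307), and Xist under 4 other alternatives (0.00295 to 0.0345).

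Same-numbered arrays were taken as paired because the design text ties the replicates to litters. As a check, deviations from the group means correlated at a mean r of 0.33 over the 18 pairs of arrays with the same number, from 0.0044 to 0.54 with 17 above 0.1. All 12 arrays correlated best with their own number, and Kdm5d and Uty on the Y chromosome were lowest in replicate 2 in all 4 groups, whereas the lowest values of Eif2s3y and Xist lay in different replicates from group to group. Genes are not independent replicates in these correlations. The replicate block, an alternative fixed beforehand, adds the litter to the fit and leaves 6 residual degrees of freedom.

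Further alternatives were only genes above the median level, the mean of all probe sets of a gene, quantile normalization of the 12 columns again, a mean-variance trend with a robust prior, only the groups of a comparison in the fit, all probe sets tested singly, and each array left out in turn. A litter block together with an estimated correlation was added after the data were seen. Chance values for comparisons that share arrays came from 20 simulations of unchanged groups.

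The fits were tested on simulated data of 19938 genes with 200 changed. At 1.5-fold, 2-fold and 4-fold they recovered 191, 198 and 200 for Aβ42 alone against vehicle, 194, 199 and 200 for AE1-329 added to Aβ42, 193, 199 and 200 for AE1-329 alone, 194, 198 and 200 for Aβ42 with AE1-329 against AE1-329 alone, and 152, 198 and 199 for the interaction, none in the wrong direction, with 3 to 20 false calls. In 5 simulations without any change, limma called 0 genes, except 1 in 1 run for Aβ42 with AE1-329 against AE1-329 alone. For Aβ42 alone against vehicle, a simulated slope of 0.8 was estimated as 0.797, and 2 of 2 shifted lists and 1 unshifted list were called.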

Results

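Transcript levels were measured on 12 microarrays in primary microglia, the resident macrophages of the brain, which were isolated from C57BL/6J mice on postnatal day 7 with magnetic beads against CD11b and cultured for 3 days. The cells were treated for 6 h with oligomeric Aβ42, the aggregating peptide of Alzheimer's disease plaques, at 10 µM, with AE1-329, an agonist of the prostaglandin E2 receptor EP4, at 100 nM, with both, or with the 2 vehicles. Each of the 4 treatments was applied to cells of 3 litters, which served as the replicates (n = 3 arrays per group), and 19938 genes were compared. Changes are log2 differences between group means ± the standard error of the limma fit, and the number of arrays limits their precision. Array medians lay between 6.97 and 7.05 log2 units. The first principal component held 65.9% of the variance and parted all arrays with Aβ42 from all arrays without it, and the second held 13.3% and parted all arrays with AE1-329 from all arrays without it. The median standard deviation between replicates was 0.109 log2 units in vehicle cultures and between 0.063 and 0.066 in the other groups. Vehicle replicate 1 had 18 genes at least 1 log2 unit above both other vehicle arrays, among them Hdac4 and Paip1, and replicate 3 of AE1-329 alone had 16 such genes, 15 of which rose with Aβ42. Both sets were picked out after their values were seen. No other array had more than 1 such gene. At least 1 log2 unit below both others of their group lay 13 genes in replicate 3 of AE1-329 alone, 12 in vehicle replicate 3, 5 and 4 in replicate 3 of Aβ42 alone and of the combined treatment, and at most 2 in any other array.

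The first comparison asked how 6 h of Aβ42 alone changed microglial transcripts. Cd69, an early activation antigen, rose by 6.99 ± 0.49 on the log2 scale (127-fold), and Cxcl2, a chemokine that draws in neutrophils, rose by 6.95 ± 0.10 (124-fold). In vehicle Cd69 (5.06) and Cxcl2 lay below the array medians, and with signal over background unknown, folds of dim genes may be lower bounds. Clec4e, a C-type lectin receptor, rose 63.2-fold, Il1b, the gene of interleukin-1 beta, 57.3-fold, and Acod1, whose product makes itaconate, 47.6-fold. The other genes with the highest changes were Il12b, a subunit of interleukin-12 (5.06 ± 0.14), the chemokine gene Ccl5 (4.72 ± 0.34), the acute-phase gene Saa3 (4.67 ± 0.18), the interferon-induced chemokine gene Cxcl10 (4.63 ± 0.67) and Olr1, a receptor of oxidized low-density lipoprotein (4.43 ± 0.13).

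The largest falls were in Rnf144b, an E3 ubiquitin ligase gene (-3.06 ± 0.06, 8.34-fold lower), in Abcd2, a peroxisomal fatty acid transporter gene (-3.02 ± 0.10), and in Zfp36l1, which encodes an mRNA decay factor (-3.00 ± 0.14). The next were Arrdc3 (-2.75 ± 0.10), the regulator of G protein signalling Rgs2 (-2.52 ± 0.10), the lysophosphatidylserine receptor Gpr34 (-2.51 ± 0.08), Slc46a3 (-2.50 ± 0.10), hepatocyte growth factor Hgf (-2.50 ± 0.08), the chemokine receptor Cxcr4 (-2.50 ± 0.05) and the sialyltransferase St8sia4 (-2.47 ± 0.07). Among the genes followed in every comparison, Tnf rose by 3.95 ± 0.09 and Il6 by 3.96 ± 0.12. Ptgs2, which encodes cyclooxygenase-2, rose by 3.16 ± 0.23, the chemokine gene Ccl2 by 1.47 ± 0.16, inducible nitric oxide synthase Nos2 by 1.58 ± 0.08, and the interferon regulatory factors Irf1 and Irf7 by 1.73 ± 0.10 and 1.69 ± 0.32. Cybb, the catalytic subunit of the phagocyte oxidase, rose by 0.41 ± 0.06. Ptger2, the gene of the EP2 receptor, fell by 0.56 ± 0.09, whereas Ptger4, the gene of the EP4 receptor, did not pass (-0.11 ± 0.07, adjusted p = 0.309). The anti-inflammatory cytokine gene Il10 rose by 0.48 ± 0.14 (adjusted p = 0.0260), a call that ended, at adjusted p between 0.0547 and 0.0878, when any 1 of the 3 Aβ42-alone arrays or vehicle replicate 2 was left out, when the arrays were quantile normalized again (0.0663) and when all 35556 probe sets were tested (0.0571).

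Of the NF-kB target genes, which answer to a central inflammatory transcription factor, 21 of 21 rose (median log2 change 2.58, adjusted p = 4.44e-37), including Cd40 (4.08 ± 0.08), Nfkbiz (3.50 ± 0.08) and Icam1 (3.46 ± 0.08). Among cytokine genes 13 of 20 rose and 7 did not pass (adjusted p = 5.07e-12). Among chemokine genes 16 of 20 rose, 1 fell and 3 did not pass (adjusted p = 5.07e-12). Cxcl1 changed by 3.23 ± 0.10, Cxcl3 by 2.47 ± 0.14 and Ccl4 by 2.32 ± 0.10. Of the type I interferon-stimulated genes 29 of 30 rose and 1 did not pass, with a median of 1.15 (adjusted p = 9.42e-17, and adjusted p = 0.241 with an estimated correlation). Mx2 (2.53 ± 0.21) and Parp14 (1.76 ± 0.13), both antiviral effector genes, and the RNA sensor Ifih1 (1.52 ± 0.11) were among them. Of the interferon-gamma and GTPase genes 13 of 15 rose, 1 fell and 1 did not pass (14 rose and 1 fell adjusted over the list alone) (adjusted p = 1.21e-10, and adjusted p = 0.0619 with an estimated correlation), including Cxcl9 (2.78 ± 0.16) and Cd274, which encodes PD-L1 (1.62 ± 0.09). Among antigen presentation genes 8 of 17 rose, 1 fell and 8 did not pass (10 rose and 1 fell adjusted over the list alone) (adjusted p = 5.17e-05), led by Cd40 and the costimulatory Cd80 (1.10 ± 0.12) and Cd83 (0.89 ± 0.05).

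Of the NADPH oxidase and nitric oxide synthase genes 6 of 9 rose and 3 did not pass (7 rose adjusted over the list alone) (adjusted p = 2.12e-06). The cytosolic oxidase subunits Ncf1 changed by 1.08 ± 0.07 and Ncf4 by 1.69 ± 0.14. Of the NRF2 target genes, an antioxidant programme, 12 of 18 rose, 1 fell and 5 did not pass (adjusted p = 3.58e-09, and adjusted p = 0.0696 with an estimated correlation). It was led by the cystine transporter Slc7a11 (3.48 ± 0.11), sulfiredoxin Srxn1 (1.62 ± 0.05) and thioredoxin reductase Txnrd1 (1.55 ± 0.07). In the unfolded protein and ATF4 response 8 of 20 rose, 3 fell and 9 did not pass (9 rose and 4 fell adjusted over the list alone) (adjusted p = 0.0490, and adjusted p = 0.292 with an estimated correlation). Herpud1, an endoplasmic reticulum degradation factor, changed by 1.88 ± 0.07 and the serine synthesis enzyme Psat1 by -0.47 ± 0.06. That list's call ended with the replicate block (adjusted p = 0.0917) and, at adjusted p between 0.0525 and 0.108, without any 1 of replicate 2 of either Aβ42 group, replicates 1 or 3 of AE1-329 alone, or vehicle replicates 1 or 2.

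Of the homeostatic microglia genes 2 of 21 rose, 7 fell and 12 did not pass (2 rose and 10 fell adjusted over the list alone) (median -0.13, adjusted p = 0.00908, and adjusted p = 0.0600 with an estimated correlation). The purinergic receptor P2ry13 (-2.43 ± 0.09), Gpr34 and the phagocytic receptor kinase Mertk (-0.95 ± 0.06) were among those that fell, while Gpr84, a receptor of medium-chain fatty acids that inflammatory stimuli induce, rose by 4.11 ± 0.13. Among genes above the median level the homeostatic list did not pass (adjusted p = 0.241). Of the cell cycle genes 21 of 27 fell and 6 did not pass (22 fell adjusted over the list alone) (median -0.57, adjusted p = 4.03e-10, and adjusted p = 0.325 with an estimated correlation). The S-phase cyclin Ccne2 changed by -1.18 ± 0.11, the transcription factors E2f1 by -0.74 ± 0.05 and Foxm1 by -0.75 ± 0.09, and the replication licensing factor Mcm2 by -0.64 ± 0.09. With the litter as a block and an estimated correlation, the cell cycle list passed (adjusted p = 0.0340) and so did the type I interferon list (adjusted p = 0.0211).

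The remaining lists of microglial programmes did not shift as groups, although members of each passed singly. Of the cAMP/CREB target genes 9 of 30 rose, 8 fell and 13 did not pass (10 rose and 11 fell adjusted over the list alone) (adjusted p = 0.976), with Rgs2 among the falls and the transcription factor Cebpb (1.69 ± 0.07) and the phosphodiesterase Pde4b (2.09 ± 0.13) among the rises. In the prostaglandin pathway 5 of 16 rose, 6 fell and 5 did not pass (6 rose and 6 fell adjusted over the list alone) (adjusted p = 0.954). The prostaglandin E synthase gene Ptges rose by 3.82 ± 0.11 while Hpgd, the degrading enzyme, fell by 1.42 ± 0.06. Of the scavenger and phagocytic receptors 6 of 26 rose, 11 fell and 9 did not pass (7 rose and 12 fell adjusted over the list alone) (adjusted p = 0.870). Tlr2 changed by 2.40 ± 0.05 and Marco by 1.71 ± 0.07. Among amyloid-degrading enzymes 3 of 13 rose, 3 fell and 7 did not pass (adjusted p = 0.613), and the matrix metalloproteinases Mmp14 (3.01 ± 0.09) and Mmp9 (2.55 ± 0.13) rose while urokinase Plau fell by 1.36 ± 0.15. Of the disease-associated microglia genes 2 of 23 rose, 4 fell and 17 did not pass (adjusted p = 0.750), and of the complement genes 2 of 16 rose, 2 fell and 12 did not pass (adjusted p = 0.954). Of the cell motility and adhesion genes 7 of 18 rose, 5 fell and 6 did not pass (adjusted p = 0.245). The integrins Itga5 changed by 1.85 ± 0.07 and Itgal by 1.92 ± 0.09. In cholesterol biosynthesis 3 of 19 rose, 1 fell and 15 did not pass (4 rose and 1 fell adjusted over the list alone) (adjusted p = 0.379). Among LXR and lipid efflux genes 3 of 12 rose, 3 fell and 6 did not pass (4 rose and 3 fell adjusted over the list alone) (adjusted p = 0.954). The nuclear receptor Nr1h3 changed by 1.55 ± 0.13. In glycolysis and hypoxia 6 of 18 rose, 5 fell and 7 did not pass (7 rose and 5 fell adjusted over the list alone) (adjusted p = 0.281). Among alternative activation genes 6 of 19 rose, 2 fell and 11 did not pass (7 rose and 2 fell adjusted over the list alone) (adjusted p = 0.132). The cytokine suppressor Socs3 changed by 3.48 ± 0.14.

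Markers of other cells that a brain preparation could hold did not shift as lists with Aβ42. Of the astrocyte markers 1 of 12 rose and 11 did not pass (adjusted p = 0.520). Of the oligodendrocyte lineage markers 2 of 11 fell and 9 did not pass (1 fell adjusted over the list alone) (adjusted p = 0.870), and of the endothelial and mural markers 1 of 13 fell and 12 did not pass (adjusted p = 0.954). Of the monocyte and border macrophage markers 2 of 11 rose, 1 fell and 8 did not pass (adjusted p = 0.954). Among neutrophil markers 2 of 12 rose, 3 fell and 7 did not pass (adjusted p = 0.976). Lcn2, which inflammation also induces in other cells, changed by 1.89 ± 0.30 and Csf3r by -0.52 ± 0.07. Of the lymphocyte and erythroid markers 1 of 9 rose, 1 fell and 7 did not pass (1 rose and 2 fell adjusted over the list alone) (adjusted p = 0.954). None of the 12 neuron markers passed in limma, 0 of them had an unadjusted p under 0.05, and fry gave adjusted p = 0.903.

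In all, 5100 of the 19938 genes passed limma's test between Aβ42 alone and vehicle, 2140 higher and 2960 lower, and 341 of these rose and 188 fell at least 2-fold. Groups did not overlap for 35.0% of genes, where chance gives 10%. Camera shifted 11 of 29 lists, 9 up and 2 down, and the calls of NF-kB targets, cytokines, chemokines, NADPH oxidase and antigen presentation also held with an estimated correlation. With the litter block as well the NADPH oxidase call ended (adjusted p = 0.0684). In 8 lists, none of them shifted, the signs of median, mean and test differed: cAMP/CREB targets, scavenger receptors, amyloid-degrading enzymes, the prostaglandin pathway, LXR genes, neuron markers, monocyte markers and lymphocyte markers.

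**Figure D1:**
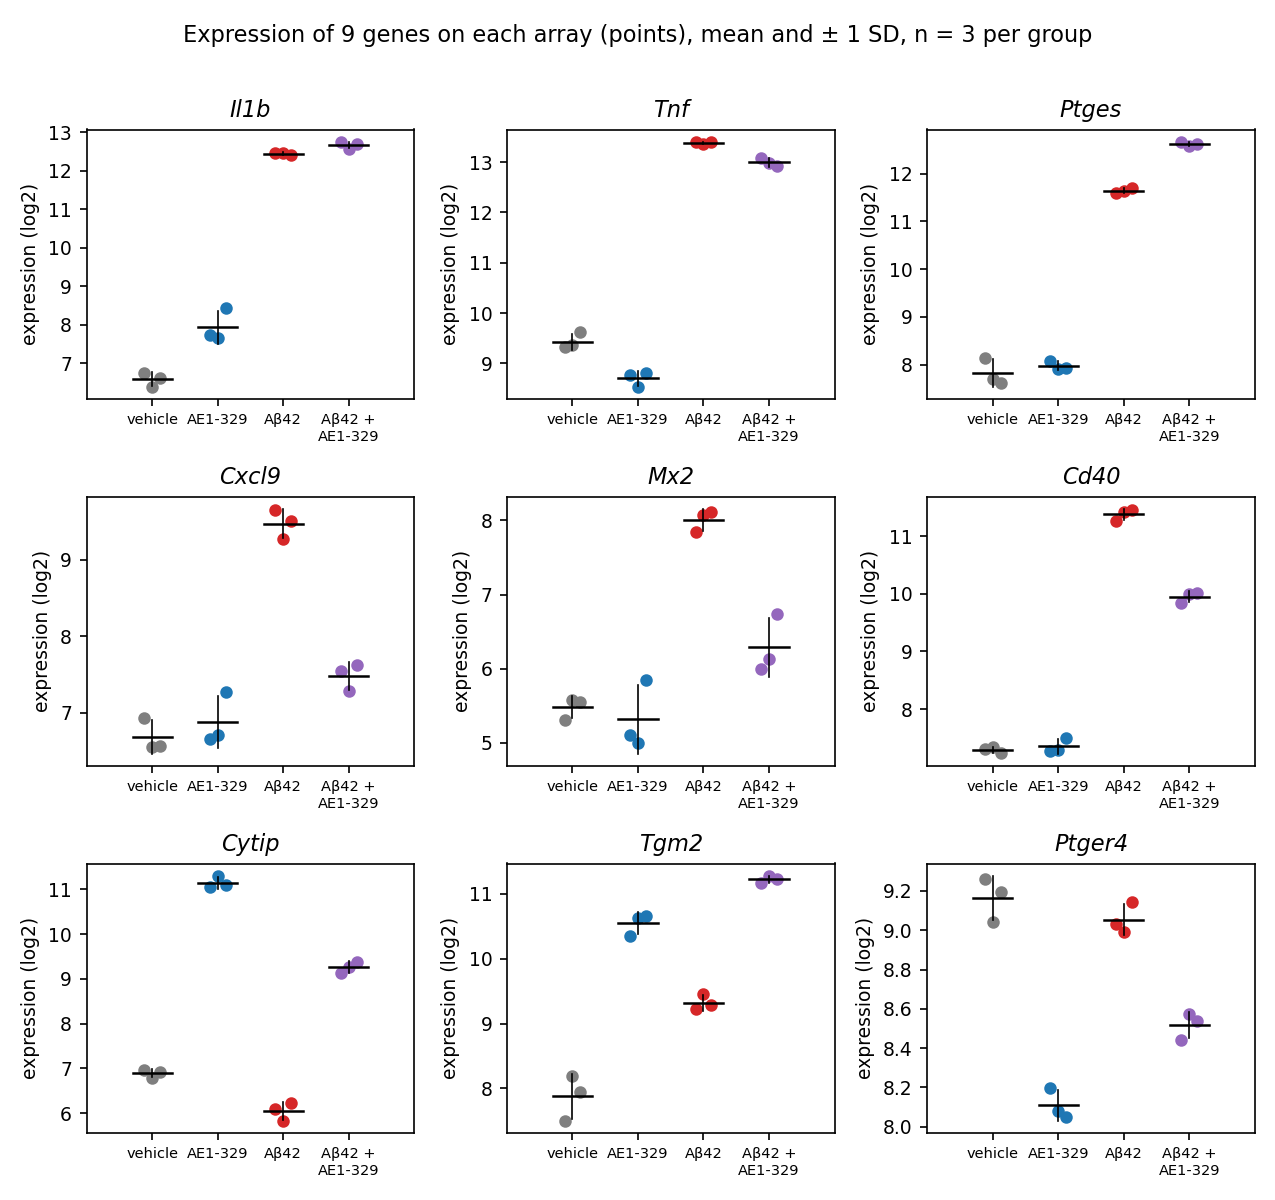
Log2 expression of 9 genes on each of the 12 arrays, 3 arrays per group, with the horizontal bar at the group mean and the vertical bar at ± 1 standard deviation. Il1b and Tnf were high in both groups with Aβ42, Cxcl9, Mx2 and Cd40 were lower with AE1-329 than without it among the Aβ42 cultures, and Cytip and Tgm2 were higher with AE1-329 in both settings.

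The second comparison asked what AE1-329 changed in microglia that were also given Aβ42. Cxcl9, a T-cell chemokine induced by interferon-gamma, fell by 1.99 ± 0.16 (3.97-fold lower). The antiviral GTPase Mx2 (-1.72 ± 0.21), the aggrecanase Adamts4 (-1.52 ± 0.14), the chemokine Ccl12 (-1.46 ± 0.10), the costimulatory receptor Cd40 (-1.43 ± 0.08), the growth factor Pdgfb (-1.41 ± 0.11) and Ch25h, which makes 25-hydroxycholesterol (-1.34 ± 0.15), followed. Mx1 fell by 1.68 ± 0.37, Usp18, a negative regulator of interferon signalling, fell by 1.46 ± 0.35 and Ifit3b fell by 1.33 ± 0.39. Mx1 lost its call without replicate 2 of Aβ42 with AE1-329 (adjusted p = 0.0505) or replicate 3 of Aβ42 alone (0.0506). Usp18 lost it without replicates 1 or 2 of the combined treatment or replicates 2 or 3 of Aβ42 alone (0.0534 to 0.0826), and Ifit3b without replicates 1 or 2 of the combined treatment, any 1 of the Aβ42-alone replicates, replicate 2 of AE1-329 alone or vehicle replicate 2 (0.0543 to 0.191). Usp18 also lost it with a mean-variance trend and robust prior (0.0634), and Ifit3b with that prior (0.131), with quantile normalization again (0.0661) and over all probe sets (0.109).

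The genes that rose most with AE1-329 on top of Aβ42 were led by Cytip, which encodes a regulator of cytohesin and cell adhesion, at 3.21 ± 0.10 (9.24-fold). Stat4 rose by 2.58 ± 0.09, the receptors Trem1 and Treml4 of the TREM family by 2.57 ± 0.13 and 2.53 ± 0.15, mitochondrial arginase Arg2 by 2.15 ± 0.10, Spic, a transcription factor of iron-recycling macrophages, by 2.06 ± 0.13, and Mxi1, a MAX-binding repressor, by 1.97 ± 0.06. Transglutaminase Tgm2 (1.91 ± 0.14), Carmil1 (1.83 ± 0.07) and Edil3 (1.81 ± 0.11) followed. Of the genes followed throughout, Ccl2 fell by 0.82 ± 0.16, Irf1 fell by 0.71 ± 0.10 and Ptger4 fell by 0.54 ± 0.07, and Ptger2 rose by 0.57 ± 0.09. Tnf fell by 0.39 ± 0.09 (adjusted p = 0.010), and it did not pass without replicate 3 of the combined treatment (adjusted p = 0.0511). Nos2 fell by 0.30 ± 0.08 (adjusted p = 0.0229), a call lost without replicates 1 or 3 of the combined treatment or replicates 2 or 3 of Aβ42 alone (0.0729 to 0.108) and over all probe sets (0.0504). Il6 rose by 0.42 ± 0.12 (adjusted p = 0.0375), a call lost without any 1 of the 6 arrays compared (0.0541 to 0.167) and over all probe sets (0.0844). Il1b (0.23 ± 0.16, adjusted p = 0.504), Il10 (0.23 ± 0.14, 0.442), Ptgs2 (-0.39 ± 0.23, 0.381) and Cybb (-0.06 ± 0.06, 0.673) did not pass. Irf7 did not pass either (-0.64 ± 0.32, adjusted p = 0.287) but passed with the replicate block (0.0276), and with only the 6 arrays of the comparison in the fit Irf7 (0.0253), Il1b (0.0289) and Ptgs2 (0.00370) passed.

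Both interferon lists shifted down in camera when AE1-329 was added. Of the type I interferon-stimulated genes 20 of 30 fell and 10 did not pass (24 fell adjusted over the list alone) (median -0.68, adjusted p = 1.26e-15, and adjusted p = 0.294 with an estimated correlation). Ifih1 changed by -0.87 ± 0.11, Herc6 by -0.72 ± 0.12 and Trim30a by -0.49 ± 0.08. Of the interferon-gamma and GTPase genes 8 of 15 fell and 7 did not pass (13 fell adjusted over the list alone) (median -0.61, adjusted p = 5.74e-09, and adjusted p = 0.150 with an estimated correlation), including the immunity-related GTPase Irgm1 (-1.16 ± 0.18) and the transcription factor Irf8 (-0.35 ± 0.06). Of the chemokine genes 2 of 20 rose, 5 fell and 13 did not pass (3 rose and 6 fell adjusted over the list alone) (adjusted p = 0.0175, and adjusted p = 0.268 with an estimated correlation). Ccl4 changed by -0.72 ± 0.10 and the neutrophil chemokine Cxcl3 by 1.16 ± 0.14. The list's call ended without replicate 2 of the combined treatment (adjusted p = 0.0742). Of the disease-associated microglia genes 5 of 23 fell and 18 did not pass (6 fell adjusted over the list alone) (adjusted p = 0.00808, and adjusted p = 0.294 with an estimated correlation). The receptor kinase Axl changed by -0.73 ± 0.07 and lipoprotein lipase Lpl by -0.43 ± 0.05.

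A further 6 lists shifted up. Of the cAMP/CREB target genes, which answer to the second messenger that EP4 raises, 16 of 30 rose, 6 fell and 8 did not pass (median 0.24, adjusted p = 3.31e-06). The cAMP-responsive repressor Crem changed by 1.31 ± 0.10, the nuclear receptor Nr4a1 by 1.12 ± 0.08, the phosphodiesterase Pde3b by 0.81 ± 0.06 and Egr2 by -1.05 ± 0.07. In cholesterol biosynthesis 8 of 19 rose and 11 did not pass (12 rose adjusted over the list alone) (median 0.24, adjusted p = 5.74e-09, and adjusted p = 0.0954 with an estimated correlation). Mvd changed by 0.64 ± 0.08, Hsd17b7 by 0.49 ± 0.06 and Hmgcs1 by 0.44 ± 0.06. In glycolysis and hypoxia 7 of 18 rose, 1 fell and 10 did not pass (9 rose and 1 fell adjusted over the list alone) (median 0.19, adjusted p = 3.31e-06, and adjusted p = 0.0523 with an estimated correlation). The glycolytic regulator Pfkfb3 changed by 0.97 ± 0.06, the angiogenic factor Vegfa by 0.90 ± 0.10, Bnip3 by 0.88 ± 0.10 and Hif1a by 0.61 ± 0.06. Of the NRF2 target genes 4 of 18 rose and 14 did not pass (6 rose adjusted over the list alone) (adjusted p = 7.15e-04, and adjusted p = 0.333 with an estimated correlation). The glutathione synthesis enzyme Gclc changed by 0.46 ± 0.06. Of the LXR and lipid efflux genes 2 of 12 rose, 1 fell and 9 did not pass (4 rose and 1 fell adjusted over the list alone) (adjusted p = 0.0274, and adjusted p = 0.333 with an estimated correlation). The cholesterol exporter Abca1 changed by 0.77 ± 0.05, and the call of the list ended without replicate 2 of the combined treatment (adjusted p = 0.0505) or replicate 1 of Aβ42 alone (0.0512). Of the cell cycle genes 3 of 27 rose, 1 fell and 23 did not pass (adjusted p = 0.0128, and adjusted p = 0.669 with an estimated correlation), a call that ended without replicates 2 or 3 of the combined treatment (0.0714 and 0.234) or replicate 1 of Aβ42 alone (0.424). Among genes above the median level neither the LXR nor the cell cycle list passed (0.165 and 0.180).

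The other microglial lists did not shift. Of the NF-kB target genes 6 of 21 rose, 4 fell and 11 did not pass (7 rose and 4 fell adjusted over the list alone) (adjusted p = 0.250). Bcl3 changed by 0.54 ± 0.08, Irak3 by 0.43 ± 0.06 and Icam1 by -0.55 ± 0.08. Among cytokine genes 3 of 20 rose, 4 fell and 13 did not pass (4 rose and 6 fell adjusted over the list alone) (adjusted p = 0.489, and 0.0361 as a fall among genes above the median level). The interleukins Il18 (-1.05 ± 0.12) and Il27 (-0.89 ± 0.06) fell while the receptor antagonist Il1rn rose (0.81 ± 0.12). In antigen presentation 3 of 17 rose, 4 fell and 10 did not pass (3 rose and 5 fell adjusted over the list alone) (adjusted p = 0.561). The costimulatory molecules Cd86 changed by 1.53 ± 0.07, Cd80 by 1.23 ± 0.12 and Cd83 by -0.44 ± 0.05. Of the homeostatic genes 4 of 21 fell and 17 did not pass (adjusted p = 0.168). The fractalkine receptor Cx3cr1 changed by -0.95 ± 0.10 and P2ry13 by -0.55 ± 0.09. In the prostaglandin pathway 3 of 16 rose, 4 fell and 9 did not pass (3 rose and 5 fell adjusted over the list alone) (adjusted p = 0.559). Ptges changed by 0.97 ± 0.11 and Hpgd by -0.64 ± 0.06. Among amyloid-degrading enzymes 1 of 13 rose, 2 fell and 10 did not pass (adjusted p = 0.489), and endothelin-converting enzymes Ece1 (1.00 ± 0.06) and Ece2 (-0.53 ± 0.09) moved apart. Of the scavenger and phagocytic receptors 5 of 26 rose, 1 fell and 20 did not pass (6 rose and 2 fell adjusted over the list alone) (adjusted p = 0.181), with Tlr4 at 0.77 ± 0.09. In the unfolded protein and ATF4 response 4 of 20 fell and 16 did not pass (adjusted p = 0.181), led by Herpud1 (-0.87 ± 0.07) and Atf3 (-0.57 ± 0.08). Adjusted p was 0.346 for the NADPH oxidase list (1 of 9 fell and 8 did not pass), 0.667 for complement (2 of 16 rose and 14 did not pass), 0.268 for alternative activation (4 of 19 rose, 1 fell and 14 did not pass, 5 rose and 2 fell adjusted over the list alone) and 0.827 for motility and adhesion (3 of 18 rose, 3 fell and 12 did not pass, 4 rose and 4 fell adjusted over the list alone). Among markers of other cells, whose lists did not shift, the adhesion molecule Pecam1 (0.90 ± 0.08) and the lectin receptor Clec12a (-0.51 ± 0.10) passed.

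In limma, 2199 genes passed between the combined treatment and Aβ42 alone, 1194 higher and 1005 lower, with 50 up and 36 down at least 2-fold, and groups did not overlap for 32.0% of genes against 10% by chance. Camera shifted 10 of 29 lists, 6 up and 4 down, and the cAMP/CREB call alone held with an estimated correlation (adjusted p = 0.0331). With the litter block as well that call ended too (adjusted p = 0.0894), and none held. In 6 lists, none shifted, the signs of median, mean and test differed, namely complement, antigen presentation, motility, endothelial, neutrophil and monocyte markers.

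**Figure D2:**
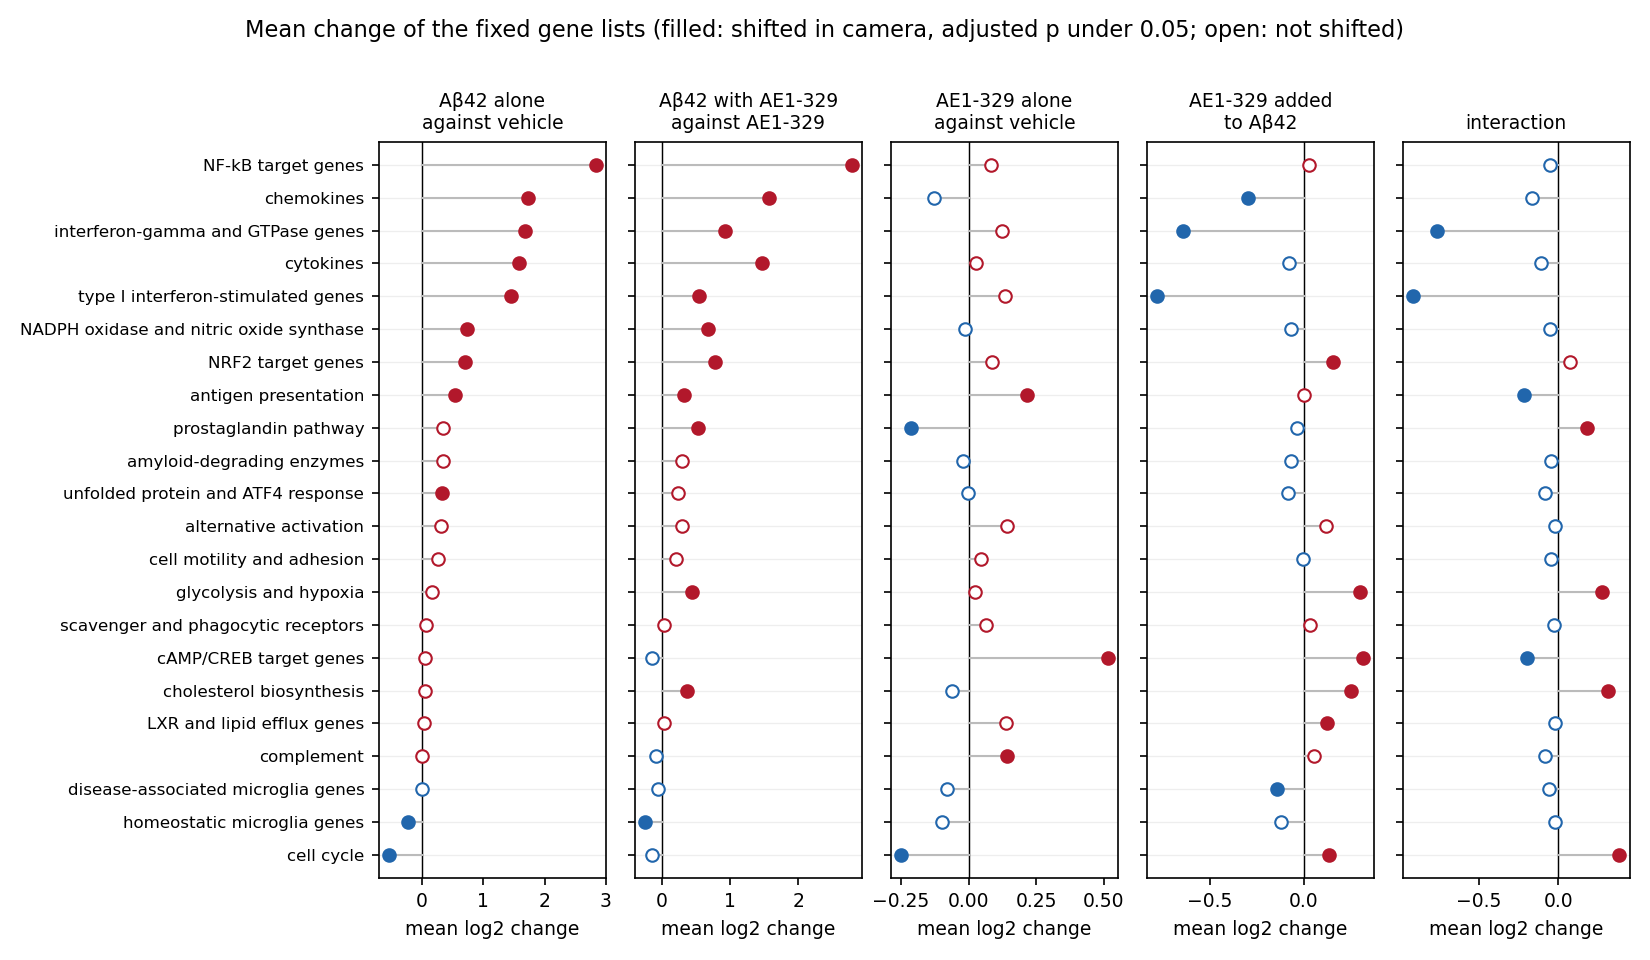
Mean log2 change of the measured members of 22 fixed gene lists in the 4 pairwise comparisons and the interaction, where filled circles mark lists shifted in camera at an adjusted p under 0.05 and open circles lists that were not, and each panel has its own scale. NF-kB targets rose by 2.83 with Aβ42 alone and by 2.78 with Aβ42 in the presence of AE1-329, whereas type I interferon-stimulated genes rose by 1.46 and 0.54.

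The third comparison asked what AE1-329 alone did against vehicle. Cytip rose most, by 4.26 ± 0.10 (19.2-fold), followed by Tgm2 (2.67 ± 0.14), the integrin ligand Edil3 (2.33 ± 0.11), the protease inhibitor Ctla2a (2.31 ± 0.20) and the nuclear receptor Nr4a2 (2.19 ± 0.11). Cnnm2, a magnesium transport gene (1.97 ± 0.05), the costimulatory Cd80 (1.82 ± 0.12), the cAMP phosphodiesterase Pde7b (1.82 ± 0.11), the triglyceride synthesis enzyme Dgat1 (1.57 ± 0.08) and Trem1 (1.53 ± 0.13) completed the 10 highest. The largest falls were in Nanos1 (-1.78 ± 0.06, 3.45-fold lower), urokinase Plau (-1.5 ± 0.15), Ch25h (-1.45 ± 0.15), the Rac regulator Chn2 (-1.44 ± 0.07) and the histone deacetylase Hdac9 (-1.43 ± 0.07). Arap2 (-1.39 ± 0.11), Ccl4 (-1.38 ± 0.10), the inhibitory receptor Lair1 (-1.36 ± 0.09), AI504432 (-1.23 ± 0.24) and Efr3b (-1.19 ± 0.08) followed.

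Ptger4, the gene of the agonist's own receptor, fell by 1.06 ± 0.07 (adjusted p = 8.97e-07), and Ptger2 did not pass (-0.11 ± 0.09, adjusted p = 0.581). Tnf fell by 0.73 ± 0.09 and Ccl2 fell by 1.07 ± 0.16, whereas Il1b rose by 1.34 ± 0.16. Il6 (-0.06 ± 0.12), Il10 (-0.02 ± 0.14), Nos2 (0.06 ± 0.08), Cybb (-0.06 ± 0.06) and Ptgs2 (0.29 ± 0.23) did not pass. Irf1 (0.20 ± 0.10, adjusted p = 0.285) and Irf7 (0.58 ± 0.32, 0.347) did not pass except with the replicate block (0.0499 and 0.0459) and, for Irf7, without vehicle replicate 3 (0.0430).

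With AE1-329 alone, 5 lists shifted. Of the cAMP/CREB target genes 18 of 30 rose, 2 fell and 10 did not pass (19 rose and 3 fell adjusted over the list alone) (median 0.49, adjusted p = 6.77e-13). Nr4a1 changed by 1.51 ± 0.08, Crem by 1.52 ± 0.10 and the phosphodiesterase Pde4d by 1.41 ± 0.09 beside Nr4a2. In the prostaglandin pathway 5 of 16 fell and 11 did not pass (median -0.10, adjusted p = 0.00161, and adjusted p = 0.0544 with an estimated correlation). The phospholipase Pla2g4a changed by -0.85 ± 0.06, the prostaglandin D synthase Hpgds by -0.61 ± 0.08 and Hpgd by -0.45 ± 0.06. Of the cell cycle genes 8 of 27 fell and 19 did not pass (9 fell adjusted over the list alone) (median -0.13, adjusted p = 6.65e-05, and adjusted p = 0.745 with an estimated correlation). The cyclins Ccnd1 changed by -0.96 ± 0.10 and Ccne2 by -0.73 ± 0.11 and the replication clamp Pcna by -0.57 ± 0.09. Of the complement genes 4 of 16 rose and 12 did not pass (adjusted p = 0.0361, and adjusted p = 0.162 with an estimated correlation). The anaphylatoxin receptors C5ar2 changed by 0.71 ± 0.06 and C5ar1 by 0.30 ± 0.05, and the call of the list ended without vehicle replicate 2 (adjusted p = 0.129) or among genes above the median level (0.0604). Of the antigen presentation genes 3 of 17 rose and 14 did not pass (adjusted p = 0.050, and adjusted p = 0.490 with an estimated correlation). Cd86 changed by 1.29 ± 0.07 and Cd83 by 0.30 ± 0.05 beside Cd80. The list's call ended among genes above the median level (0.0914) and, at adjusted p between 0.0512 and 0.163, without any 1 of 8 arrays, which were the 3 of Aβ42 alone, replicates 2 and 3 of the combined treatment, replicate 3 of AE1-329 alone and vehicle replicates 1 and 2.

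The interferon lists did not pass with AE1-329 alone. None of the 30 type I interferon-stimulated genes passed in limma, 3 had an unadjusted p under 0.05, and 5 rose with the replicate block (median log2 change 0.12, adjusted p = 0.213 by camera, 0.671 by fry and 0.0388 by camera with the block). Replicate 3 of AE1-329 alone stood apart in these genes, with Cxcl10 at 10.92 against 7.29 and 7.61 in the other replicates and Rsad2 at 11.04 against 8.37 and 8.87. Without replicates 1 or 2 of AE1-329 alone or vehicle replicate 3 the list passed as higher (adjusted p = 0.00232, 0.0475 and 0.00495, litters unbalanced). Of the interferon-gamma and GTPase genes 1 of 15 rose and 14 did not pass (adjusted p = 0.271), and this list passed without replicate 2 of AE1-329 alone (0.0475). The LXR and lipid efflux list, in which 1 of 12 rose and 11 did not pass (3 rose and 1 fell adjusted over the list alone), missed the threshold (adjusted p = 0.0676) and passed with the block (0.0413), without replicate 2 of AE1-329 alone (0.0486) and without vehicle replicate 3 (0.0167), with Abca1 at 1.07 ± 0.05.

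In the lists that did not shift, Tnfaip3, which restrains NF-kB, fell by 0.97 ± 0.06 among the NF-kB target genes (5 of 21 rose, 4 fell and 12 did not pass, 8 rose and 4 fell adjusted over the list alone, adjusted p = 0.213). The cytokine Il15 rose by 0.73 ± 0.12 (2 of 20 rose, 2 fell and 16 did not pass, 2 rose and 3 fell adjusted over the list alone, adjusted p = 0.941). Slc7a11 rose by 0.85 ± 0.11 and Srxn1 by 0.49 ± 0.05 among NRF2 targets (3 of 18 rose, 1 fell and 14 did not pass, 3 rose and 2 fell adjusted over the list alone, adjusted p = 0.213). The co-receptor Cd14 rose by 1.12 ± 0.07 among scavenger receptors (4 of 26 rose, 1 fell and 21 did not pass, adjusted p = 0.224). Cx3cr1 (-0.82 ± 0.10), P2ry12 (-0.59 ± 0.11) and P2ry13 (-0.57 ± 0.09) fell among homeostatic genes (4 of 21 fell and 17 did not pass, 5 fell adjusted over the list alone, adjusted p = 0.271). Clec7a (-0.54 ± 0.06) and Ank (-0.53 ± 0.08) fell among disease-associated genes (5 of 23 fell and 18 did not pass, adjusted p = 0.213). Ece1 rose by 1.14 ± 0.06 and Mmp14 by 0.60 ± 0.09 among amyloid-degrading enzymes (2 of 13 rose, 3 fell and 8 did not pass, adjusted p = 0.941). Vegfa rose by 1.12 ± 0.10 and Pfkfb3 fell by 0.90 ± 0.06 in glycolysis and hypoxia (1 of 18 rose, 2 fell and 15 did not pass, adjusted p = 0.872). Actin regulator Coro1a (0.60 ± 0.08) and Cxcr4 (0.51 ± 0.05) rose among motility genes (6 of 18 rose, 3 fell and 9 did not pass, 6 rose and 4 fell adjusted over the list alone, adjusted p = 0.213). Adjusted p was 0.233 for chemokines (1 of 20 rose, 3 fell and 16 did not pass, 1 rose and 4 fell adjusted over the list alone), which passed without replicate 3 of AE1-329 alone (0.0416). It was 0.941 for the NADPH oxidase list (1 of 9 fell and 8 did not pass), 0.379 for cholesterol biosynthesis (1 of 19 rose, 2 fell and 16 did not pass), 0.715 for the unfolded protein response (1 of 20 rose, 4 fell and 15 did not pass, 3 rose and 5 fell adjusted over the list alone) and 0.271 for alternative activation (2 of 19 rose, 1 fell and 16 did not pass, 3 rose and 1 fell adjusted over the list alone). Among markers of other cells, whose lists did not shift, Pecam1 (1.22 ± 0.08) and the receptor Kdr (0.64 ± 0.10) rose and Flt1 (-0.44 ± 0.06) and Clec12a (-0.88 ± 0.10) fell.

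In all, 2026 genes passed in limma between AE1-329 alone and vehicle, 939 higher and 1087 lower, with 54 up and 21 down at least 2-fold, and groups did not overlap for 22.9% of genes against 10% by chance. Without vehicle replicate 3 more genes were higher than lower (1107 and 1004), and the share of higher calls ran from 41.6% to 52.4% with 1 array left out. Fitted to its 6 arrays alone, 970 passed. Camera shifted 5 of 29 lists, 3 up and 2 down, of which the cAMP/CREB call alone held with an estimated correlation, and 8 shifted without replicate 2 of AE1-329 alone and 3 without vehicle replicate 2. The signs of median, mean and test differed in 5 lists, none shifted (cytokines, NADPH oxidase, scavenger receptors, amyloid-degrading enzymes, glycolysis and hypoxia).

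The fourth comparison asked how Aβ42 changed microglia that also received AE1-329, against AE1-329 alone. Cxcl2 (6.97 ± 0.10, 125-fold), Cd69 (5.43 ± 0.49), Saa3 (5.38 ± 0.18), Clec4e (5.23 ± 0.11), Acod1 (5.03 ± 0.45), Il1b (4.72 ± 0.16), Ptges (4.64 ± 0.11), Il12b (4.53 ± 0.14), Il6 (4.44 ± 0.12) and Spic (4.31 ± 0.13) rose most. Rgs2 (-3.44 ± 0.10), Abcd2 (-2.62 ± 0.10), Zfp36l1 (-2.62 ± 0.14), Hgf (-2.59 ± 0.08), the Ras activator Rasgrp3 (-2.57 ± 0.09), Gpr34 (-2.42 ± 0.08), P2ry13 (-2.40 ± 0.09), Arrdc3 (-2.40 ± 0.10), Slc46a3 (-2.31 ± 0.10) and the phosphatidate phosphatase Lpin1 (-2.31 ± 0.08) fell most. Tnf rose by 4.29 ± 0.09, Ptgs2 by 2.48 ± 0.23, Ccl2 by 1.73 ± 0.16, Nos2 by 1.22 ± 0.08, Irf1 by 0.82 ± 0.10, Il10 by 0.72 ± 0.14, Cybb by 0.42 ± 0.06 and Ptger4 by 0.41 ± 0.07. Irf7 (0.47 ± 0.32, adjusted p = 0.380) and Ptger2 (0.12 ± 0.09, 0.426) did not pass. Replicate 3 of AE1-329 alone, with Cd69 at 7.40 against 4.75 and 4.89, Acod1 at 9.65 against 7.15 and 7.48 and Ccl5 at 10.03 against 8.11 and 8.59, is 1 of the 3 arrays of the reference group here.

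All but 1 of the 12 lists that shifted did so upward. Of the NF-kB target genes 21 of 21 rose (adjusted p = 2.20e-41). Tnfaip3 changed by 2.83 ± 0.06 and Nfkbiz by 3.46 ± 0.08. Among cytokine genes 11 of 20 rose, 1 fell and 8 did not pass (adjusted p = 1.16e-09), with Tnfsf9, the ligand of 4-1BB, at 3.62 ± 0.11. Among chemokine genes 13 of 20 rose, 1 fell and 6 did not pass (16 rose and 1 fell adjusted over the list alone) (adjusted p = 8.53e-11). Cxcl1 changed by 3.70 ± 0.10 and Ccl4 by 2.99 ± 0.10. Of the type I interferon-stimulated genes 10 of 30 rose and 20 did not pass (13 rose adjusted over the list alone) (median 0.44, adjusted p = 2.09e-04, and adjusted p = 0.712 with an estimated correlation). Oasl1 changed by 1.59 ± 0.26, Parp14 by 1.09 ± 0.13 and Mx2 by 0.97 ± 0.21, in a list where replicate 3 of AE1-329 alone stood above its group. With the replicate block 19 members rose and 1 fell. Of the interferon-gamma and GTPase genes 10 of 15 rose, 1 fell and 4 did not pass (adjusted p = 4.36e-05, and adjusted p = 0.207 with an estimated correlation). Slfn2 changed by 1.59 ± 0.11, Cd274 by 1.30 ± 0.09 and Irf8 by -1.09 ± 0.06. The NRF2 (14 of 18 rose and 4 did not pass, adjusted p = 1.16e-11) and NADPH oxidase lists (6 of 9 rose and 3 did not pass, 7 rose adjusted over the list alone, adjusted p = 1.75e-06) rose. Glutathione reductase Gsr changed by 1.57 ± 0.06, Slc7a11 by 2.87 ± 0.11 and the proton channel Hvcn1 by 1.27 ± 0.09. In cholesterol biosynthesis 14 of 19 rose, 1 fell and 4 did not pass (median 0.44, adjusted p = 5.85e-07, and adjusted p = 0.0729 with an estimated correlation). Hsd17b7 changed by 0.70 ± 0.06, Hmgcs1 by 0.69 ± 0.06 and Sqle by 0.63 ± 0.06. In glycolysis and hypoxia 7 of 18 rose and 11 did not pass (adjusted p = 2.63e-05). Adm changed by 1.44 ± 0.08, Pfkfb3 by 1.21 ± 0.06 and Hif1a by 1.12 ± 0.06. In the prostaglandin pathway 7 of 16 rose, 2 fell and 7 did not pass (7 rose and 3 fell adjusted over the list alone) (adjusted p = 0.0333, and adjusted p = 0.0860 with an estimated correlation). Pla2g4a changed by 1.00 ± 0.06. In antigen presentation 6 of 17 rose, 1 fell and 10 did not pass (8 rose and 1 fell adjusted over the list alone) (adjusted p = 0.00171, and adjusted p = 0.0817 with an estimated correlation). Cd40 changed by 2.59 ± 0.08 and the class II gene H2-Ab1 by 0.64 ± 0.08. Of the homeostatic genes 1 of 21 rose, 8 fell and 12 did not pass (adjusted p = 0.00126). Mertk changed by -0.80 ± 0.06 and Gpr84 by 3.73 ± 0.13. Among genes above the median level the homeostatic and prostaglandin lists did not pass (adjusted p = 0.0722 for each).

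Nr4a2 fell by 1.75 ± 0.11 among the cAMP/CREB target genes, which did not shift (9 of 30 rose, 11 fell and 10 did not pass, 9 rose and 12 fell adjusted over the list alone, adjusted p = 0.181). Tlr2 rose by 2.44 ± 0.05 among scavenger receptors (6 of 26 rose, 9 fell and 11 did not pass, 6 rose and 12 fell adjusted over the list alone, adjusted p = 0.395). Mmp14 rose by 2.45 ± 0.09 among amyloid-degrading enzymes (3 of 13 rose, 2 fell and 8 did not pass, adjusted p = 0.617) and Nr1h3 by 1.25 ± 0.13 among LXR genes (3 of 12 rose, 2 fell and 7 did not pass, adjusted p = 0.890). Socs3 rose by 3.60 ± 0.14 in alternative activation (5 of 19 rose, 1 fell and 13 did not pass, adjusted p = 0.312) and Vcam1 by 1.90 ± 0.09 among motility and adhesion genes (6 of 18 rose, 6 fell and 6 did not pass, adjusted p = 0.582). C5ar2 fell by 1.59 ± 0.06 among complement genes (1 of 16 rose, 1 fell and 14 did not pass, adjusted p = 0.706), and Ank fell by 0.69 ± 0.08 among disease-associated genes (2 of 23 rose, 3 fell and 18 did not pass, adjusted p = 0.135). Herpud1 rose by 1.07 ± 0.07 in the unfolded protein response (6 of 20 rose, 2 fell and 12 did not pass, 7 rose and 3 fell adjusted over the list alone, adjusted p = 0.0639), a list that passed without replicates 2 or 3 of the combined treatment (adjusted p = 0.0398 and 0.0452). Of the cell cycle genes 1 of 27 rose and 2 fell over all genes (adjusted p = 0.0625), against 21 falls with Aβ42 alone. Adjusted over the list alone none passed in limma, while 7 had an unadjusted p under 0.05 and 13 passed with the replicate block, under which the list shifted down (adjusted p = 0.00309). It also shifted down without replicates 2 or 3 of the combined treatment (0.0280 and 0.00706), replicates 1 or 3 of Aβ42 alone (0.0335 and 0.0493) or replicate 1 of AE1-329 alone (0.00672). Among other-cell markers, whose lists did not shift in camera, Kdr fell by 1.14 ± 0.10, and Lcn2 (1.89 ± 0.30) and Clec12a (0.94 ± 0.10) rose.

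In limma 4386 genes passed between the combined treatment and AE1-329 alone, 1948 higher and 2438 lower, with 309 up and 162 down at least 2-fold, and groups did not overlap for 40.1% of genes against 10% by chance. Of the 12 list calls, 7 held with an estimated correlation, and 3 of these ended with the litter block as well, namely NADPH oxidase and glycolysis (adjusted p = 0.0771 for each) and homeostatic genes (0.0742). The signs of median, mean and test differed in 9 lists, none shifted, which were scavenger receptors, amyloid-degrading enzymes, complement, LXR genes, alternative activation and the astrocyte, oligodendrocyte, endothelial and lymphocyte markers.

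The interaction asked whether the effect of AE1-329 differed between cultures with and without Aβ42, and its values are the AE1-329 change with Aβ42 minus the change without it. The globin-family gene Adgb (2.10 ± 0.19), Treml4 (2.10 ± 0.21), Pfkfb3 (1.87 ± 0.09), Spic (1.60 ± 0.18) and the replication fork protein gene Radx (1.56 ± 0.16) had the highest values. Pfkfb3 fell with AE1-329 alone and rose with AE1-329 on top of Aβ42. The lowest were Cxcl9 (-2.18 ± 0.23), Adamts4 (-1.76 ± 0.20), Mx2 (-1.56 ± 0.30), Cd40 (-1.49 ± 0.11) and the guanylate-binding protein Gbp7 (-1.46 ± 0.29). In the presence of Aβ42 the first 4 fell with AE1-329, while the change of Gbp7 did not pass (-0.61 ± 0.20, adjusted p = 0.0835) except with the replicate block (0.00200), only the 2 groups in the fit (0.0217) or replicate 3 of AE1-329 alone left out (0.0273). Gbp7 rose with AE1-329 alone (0.85 ± 0.20, adjusted p = 0.0167), a call that ended with only those 2 groups in the fit or without replicate 3 of AE1-329 alone or vehicle replicates 1 or 2 (0.0526 to 0.0678). The interaction calls of Mx2 and Gbp7 ended without replicates 1 or 2 of the combined treatment or replicates 2 or 3 of Aβ42 alone (adjusted p between 0.0532 and 0.0610) and over all probe sets (0.0632 and 0.0692). Ptger2 (0.68 ± 0.12, adjusted p = 0.0110) and Irf1 (-0.91 ± 0.14, 0.00434) also passed. Il1b passed (-1.12 ± 0.23, adjusted p = 0.0226) but not without replicates 2 or 3 of the combined treatment or any 1 of the Aβ42-alone replicates (0.0548 to 0.0683) or over all probe sets (0.0779). Ptger4 passed (0.52 ± 0.10, adjusted p = 0.0161) but not without replicate 2 of either Aβ42 group or of AE1-329 alone (0.0520 to 0.0563). Tnf (0.34 ± 0.12), Il6 (0.49 ± 0.17), Il10 (0.24 ± 0.20), Ccl2 (0.25 ± 0.23), Nos2 (-0.36 ± 0.11), Cybb (0.00 ± 0.08) and Ptgs2 (-0.68 ± 0.32) did not pass. Nor did Irf7 (-1.22 ± 0.45, adjusted p = 0.292), which passed with the replicate block (0.0159) and without vehicle replicate 3 (0.0495). Nos2 passed without replicate 1 of Aβ42 alone (0.0460).

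Of the type I interferon-stimulated genes, 7 of 30 had a lower response to AE1-329 with Aβ42 and 23 did not pass, against 24 lower adjusted over the list alone and 26 with the replicate block. The list mean was -0.92 (adjusted p = 2.60e-24, and adjusted p = 0.136 with an estimated correlation, which became adjusted p = 0.0291 with the block as well), and Ifih1 (-0.99 ± 0.16) and Ddx58, the RNA sensor RIG-I (-1.04 ± 0.18), were among those that passed. The mean was -0.67 without replicate 3 of AE1-329 alone, the array in which several of these genes stood above its group. Of the interferon-gamma and GTPase genes 3 of 15 were lower and 12 did not pass, with 10 lower adjusted over the list alone (mean -0.76, adjusted p = 8.64e-14). Of the cAMP/CREB target genes 4 of 30 were lower and 1 was higher, with 10 and 1 adjusted over the list alone (adjusted p = 4.95e-06), and Nr4a2 (-1.35 ± 0.16), Rgs2 (-0.92 ± 0.14) and the kinase Sik1 (-0.49 ± 0.08) were among the lower. In antigen presentation 2 of 17 were lower (4 lower and 1 higher adjusted over the list alone, adjusted p = 0.00482, and adjusted p = 0.136 with an estimated correlation), namely Cd40 and Cd83 (-0.74 ± 0.07).

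A further 4 lists had higher interactions. In the cell cycle 3 of 27 genes were higher, 9 adjusted over the list alone and 15 with the replicate block (mean 0.39, adjusted p = 1.33e-13, and adjusted p = 0.243 with an estimated correlation, which became adjusted p = 0.0400 with the block as well). E2f1 changed by 0.69 ± 0.07 and Ccne2 by 0.89 ± 0.16. In cholesterol biosynthesis 4 of 19 were higher, 11 adjusted over the list alone (mean 0.32, adjusted p = 1.68e-12). Hsd17b7 changed by 0.60 ± 0.09, Hmgcs1 by 0.52 ± 0.08 and Sqle by 0.52 ± 0.09. In glycolysis and hypoxia 3 of 18 were higher, 6 adjusted over the list alone (mean 0.28, adjusted p = 1.01e-04). Bnip3 changed by 0.89 ± 0.15 and Hif1a by 0.62 ± 0.09. In the prostaglandin pathway 5 of 16 were higher (adjusted p = 6.53e-04). Ptges changed by 0.82 ± 0.15 and Pla2g4a by 0.53 ± 0.09.

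Single genes of other lists passed, namely Tnfaip3 (0.89 ± 0.08) among the NF-kB targets (adjusted p = 0.996), the cytokines Il15 (-1.28 ± 0.17), Il18 (-1.21 ± 0.17) and Il27 (-0.88 ± 0.09), the chemokine Ccl12 (-1.19 ± 0.14), Axl (-0.64 ± 0.09), Cd14 (-0.81 ± 0.10), C5ar2 (-0.55 ± 0.09), Herpud1 (-0.81 ± 0.09) and Gsr (0.44 ± 0.08). The complement list did not shift (adjusted p = 0.0573) but passed as lower, at adjusted p between 0.0259 and 0.0487, without replicates 1 or 3 of the combined treatment, replicate 1 of Aβ42 alone, replicate 3 of AE1-329 alone or vehicle replicate 3. The endothelial list (adjusted p = 0.312) passed as lower without replicate 3 of AE1-329 alone (0.0206). Among genes above the median level complement (0.0312) and cytokines (0.00963, against 0.523 over all genes) passed as lower. In limma 389 genes passed, 206 with a higher and 183 with a lower response to AE1-329 in the presence of Aβ42, and 677 passed with the replicate block, 389 of them shared. More were lower than higher with quantile normalization again (218 and 214) and without replicate 3 of the combined treatment (135 and 129), replicate 2 of AE1-329 alone (135 and 119) or vehicle replicate 3 (194 and 186). The count was 246 without replicate 2 of Aβ42 alone, 254 without its replicate 3 and 254 without replicate 2 of AE1-329 alone. Camera shifted 8 of 29 lists, 4 up and 4 down, and 5 calls held with an estimated correlation. With the litter block as well the glycolysis call ended (adjusted p = 0.0918). In 5 lists that did not shift, namely NF-kB targets, cytokines, scavenger receptors, LXR genes and the unfolded protein response, the signs of median, mean and test differed.

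**Figure D3:**
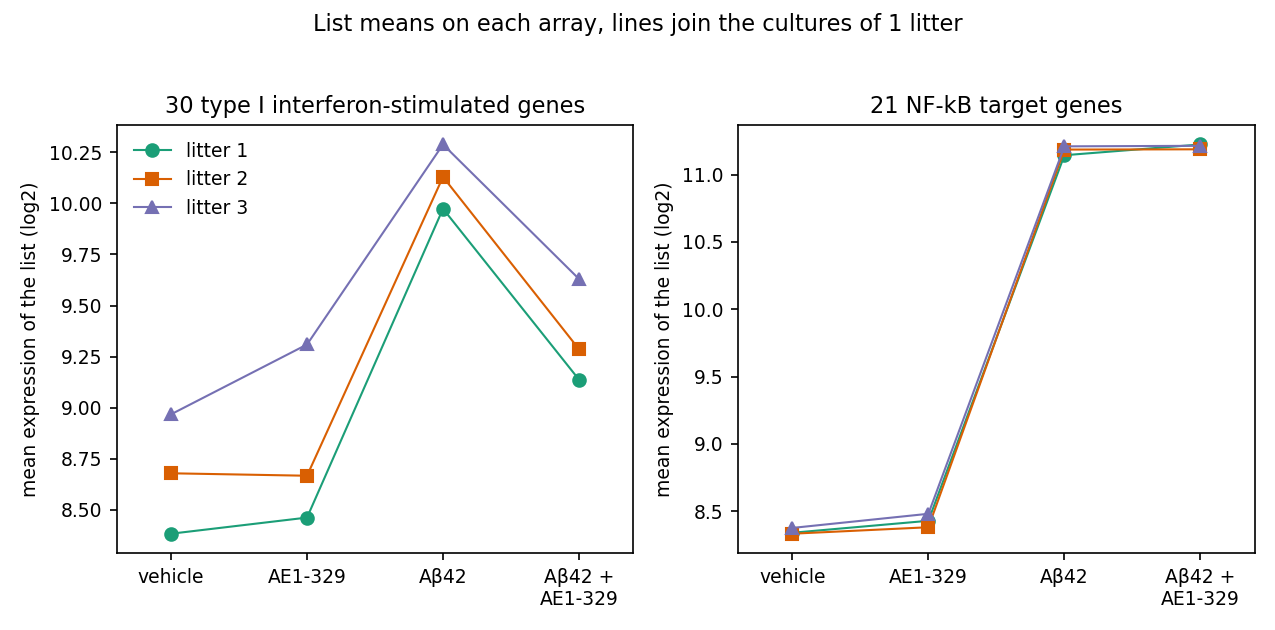
Mean log2 expression of the 30 measured type I interferon-stimulated genes and of the 21 NF-kB target genes on each of the 12 arrays, with lines joining the 4 cultures of 1 litter. In all 3 litters the interferon mean of Aβ42 with AE1-329 lay below that of Aβ42 alone, and among the vehicle cultures the AE1-329 array of litter 3 stood highest.

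The last question was how far AE1-329 moved the Aβ42 response as a whole. Of the 2140 genes that rose with Aβ42 alone, 595 (27.8%) fell when AE1-329 was added, including Cxcl9, Cd40 and Mx2 (108 by independent lists). Of the 2960 that fell, 660 (22.3%) rose with AE1-329, including Cxcr4 at 0.80 ± 0.05 (177). In both comparisons 184 rose (128) and 122 fell (149). AE1-329 alone lowered 345 of the 2140 (117), raised 434 of the 2960 (139) and shared 181 rises (101) and 357 falls (161). Sharing the vehicle arrays with Aβ42 alone favours shared rises and falls (r = 0.00336, simulated 0.50). The first 2 comparisons share the Aβ42-alone arrays, and simulations gave no calls. Across genes, not independent replicates, their r was -0.333 (simulated -0.50) and covariance -0.0261 (-0.0039). Shared arrays may give part of their overlap. When genes were chosen in 2 litters and measured in the other, 63.3% ± 4.1 (SD, n = 3 litters) of the genes raised by Aβ42 were lower with AE1-329, against 52.5% ± 9.1 of all genes. Likewise 71.3% ± 1.4 of the genes lowered by Aβ42 were higher, against 47.5% ± 9.1.

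Among the 5100 genes called for Aβ42 alone, the change with AE1-329 present followed the change without it with a least-squares slope of 0.848, from comparisons that share no array. By litter the slope was 0.822 ± 0.013 (SD, n = 3), and 0.835 ± 0.012 when genes were chosen in 2 litters and measured in the other. Per litter, the list mean with AE1-329 over that without it was 0.982 ± 0.017 (SD, n = 3) for NF-kB targets, 0.934 for cytokines, 0.904 for chemokines, 0.547 for interferon-gamma and GTPase genes and 0.364 ± 0.11 for type I interferon-stimulated genes. The AE1-329 changes with and without Aβ42, which share no array, correlated at r = 0.574 across all genes (-0.0043 in simulated unchanged groups), with 541 genes higher in both (56.2 by independent lists) and 523 lower in both (54.8). Cytip, Tgm2, Edil3 and Trem1 were among the genes higher in both. Of the 2026 genes called for AE1-329 alone, 89.9% had the same sign with Aβ42.

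**Figure D4:**
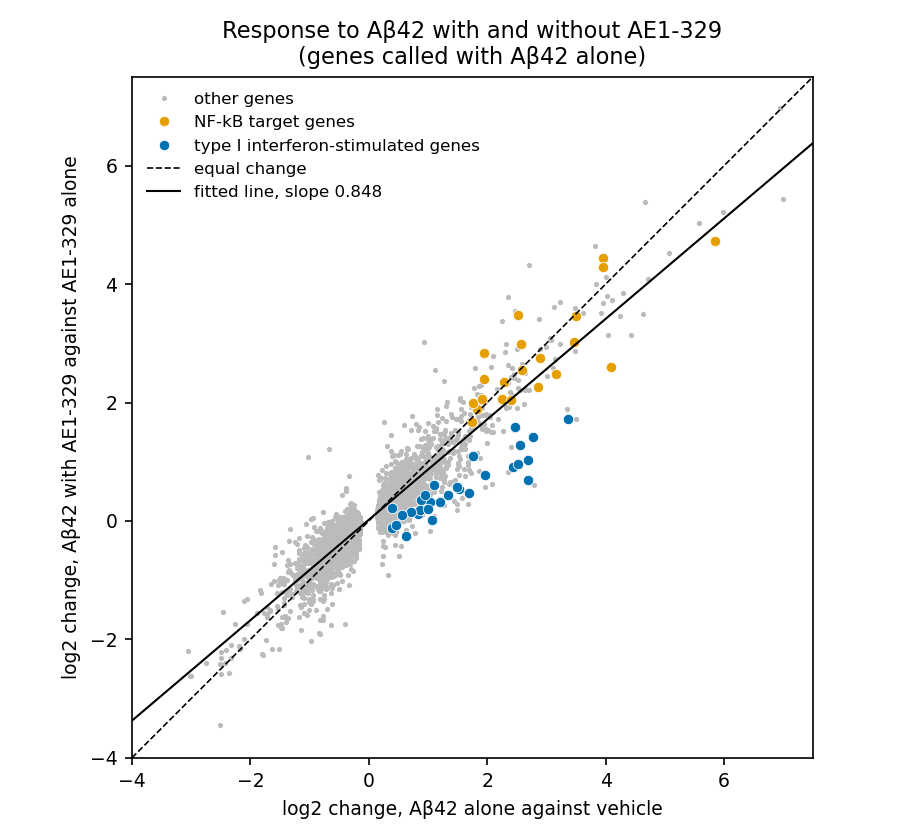
Log2 change with Aβ42 in the presence of AE1-329 against the log2 change with Aβ42 alone, 1 point per gene for the 5100 genes called with Aβ42 alone, with the fitted line of slope 0.848 and the line of equal change. Type I interferon-stimulated genes, marked in colour, lie mostly under the line of equal change. NF-kB target genes lie on both sides of it, with Cd40 below (interaction -1.49) and Tnfaip3 above (0.89).

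**Figure D5:**
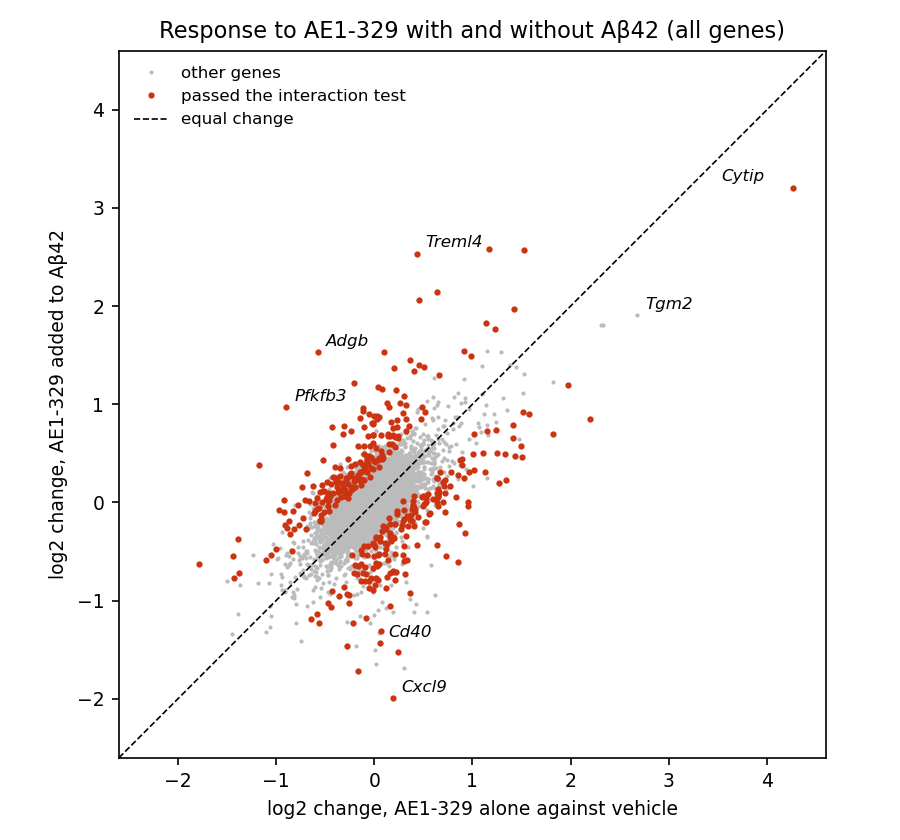
Log2 change with AE1-329 in the presence of Aβ42 against the log2 change with AE1-329 alone for all 19938 genes, 1 point per gene, with genes that passed the interaction test in colour. The changes correlated at r = 0.574 across genes, and 389 genes passed the interaction test.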

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

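Of the tests in this part, those of a weaker Aβ42 exposure and of a litter block with an estimated correlation were chosen only after the result was seen. The effect of AE1-329 differed between cultures with and without Aβ42, by the test of the difference itself, in 389 genes with limma and in 8 lists with camera. The mean log2 interaction was -0.92 for type I interferon-stimulated genes, -0.76 for interferon-gamma and GTPase genes, -0.21 for antigen presentation and -0.20 for cAMP/CREB targets. It was 0.39 for the cell cycle, 0.32 for cholesterol biosynthesis, 0.28 for glycolysis and hypoxia and 0.18 for the prostaglandin pathway. With an estimated correlation the calls of the type I interferon, antigen presentation (adjusted p = 0.136 for each) and cell cycle lists (adjusted p = 0.243) ended. With the litter block as well these 3 passed (adjusted p = 0.0291, 0.0443 and 0.0400), and that of glycolysis ended (0.0918).

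The same test set apart single genes. The response to AE1-329 was lower with Aβ42 for the chemokines Cxcl9 (-2.18) and Ccl12 (-1.19), the interferon-induced Mx2 (-1.56), Gbp7 (-1.46), Ddx58 (-1.04) and Ifih1 (-0.99), the cytokines Il15 (-1.28), Il18 (-1.21), Il1b (-1.12) and Il27 (-0.88), the surface molecules Cd40 (-1.49), Cd14 (-0.81), Cd83 (-0.74), Axl (-0.64) and C5ar2 (-0.55), and Adamts4 (-1.76), Nr4a2 (-1.35), Rgs2 (-0.92), Irf1 (-0.91), Herpud1 (-0.81) and Sik1 (-0.49). It was higher for Adgb and Treml4 (2.10 for each), Pfkfb3 (1.87), Spic (1.60), Radx (1.56), Tnfaip3, Bnip3 and Ccne2 (0.89 for each), Ptges (0.82), E2f1 (0.69), Ptger2 (0.68), Hif1a (0.62), Hsd17b7 (0.60), Pla2g4a (0.53), Ptger4, Hmgcs1 and Sqle (0.52 for each) and Gsr (0.44). The calls of Il1b, Mx2, Gbp7 and Ptger4 ended without any 1 of 5, 4, 4 and 3 arrays. Outside the comparisons, which used probe sets with 1 gene symbol, 1118 of the 13767 other probe sets passed between Aβ42 alone and vehicle, 459 higher and 659 lower, a signal in values the comparisons leave out.

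Other groupings of the arrays were tested for each count. For a comparison of 3 arrays with 3 the 10 splits are too few for a share under 0.05. The real and the highest other count of genes were 5100 and 0 for Aβ42 alone, 2199 and 0 for AE1-329 added to Aβ42, 2026 and 1 for AE1-329 alone, and 4386 and 0 for Aβ42 with AE1-329 against AE1-329 alone, with 1 of 10 splits as large in each. For shifted lists the counts were 11 and 12, 10 and 8, 5 and 10, and 12 and 13 in the same order, with 2, 1, 3 and 3 of 10 splits as large, and among the 4 splits that part as many litter pairs as the real one the highest other counts were 12, 5, 2 and 10. For the interaction 3 of 100 drawn splits, the real one included, gave 389 genes or more, a share under 0.05. Both larger splits (558 and 536) kept or turned all AE1-329 labels of the Aβ42 arrays and mixed those of the vehicle arrays, which leaves part of the effect in place. Of the 21 drawn splits that part as many pairs, 2 gave 389 or more, the real one and that of 536, so the splits cannot decide on chance. For interaction lists 13 of 100 splits gave 8 or more (highest 10, and 8 among those that part as many pairs), and chance cannot be excluded. For the 595 genes raised by Aβ42 and lowered by AE1-329, 1 of 100 splits was as large (highest other 246). The splits mix Aβ42 with vehicle arrays and cannot decide on chance. The 16 parting as many pairs (highest other 246) are also too few.

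With AE1-329 20 of 30 type I interferon-stimulated genes fell in cultures with Aβ42, and 7 passed for the interaction (mean -0.92). Both list calls were lost with an estimated correlation (adjusted p = 0.294 and 0.136), and with the litter block as well the interaction passed (adjusted p = 0.0291). A weaker Aβ42 exposure that scales all genes alike is argued against, because the list kept 0.364 ± 0.11 (SD, n = 3 litters) of its Aβ42 change with AE1-329 while the slope over all called genes was 0.82 and NF-kB targets kept 0.982, although an exposure to which interferon genes answer more steeply was not tested. A normalization that shifts genes of this brightness is argued against, because 0 of 10000 random lists matched on mean level reached the observed value (lowest -0.16). An added level of a litter cancels by design, since each litter was in all 4 groups, and the interaction within litters was -0.92, -0.83 and -1.0. Chance stays open, as splits cannot decide it. Of all 200, 11 with the real one were as large (0.92 against at most 1.26). In 7 all Aβ42-array labels were kept or turned, which leaves part of the effect in place. The highest other of the 32 that part as many pairs was 0.93. An effect of AE1-329 itself also stays open, as untested.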

How the results depend on the processing

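The replicate block with an estimated correlation was chosen only after the result was seen. No named gene that passed, slope or correlation changed sign under the alternatives run for it. The balance of higher and lower calls turned for AE1-329 alone under 1 alternative and for the interaction under 4, as given with those counts. With the replicate block the interaction count rose from 389 to 677 genes, while the other counts moved by less than 1.5 times (5697, 2683, 2520 and 4998 genes for Aβ42 alone, AE1-329 added to Aβ42, AE1-329 alone and Aβ42 with AE1-329, and 10, 10, 7, 13 and 8 lists with the interaction last). Beyond the lists, the 3 sex-linked genes and the Irf1, Irf7 and Gbp7 calls named with their results, this paired fit changed no other call of a named gene. Fitted to their 6 arrays alone, comparisons with vehicle gave fewer genes (970 for AE1-329 alone, 967 shared) and other pairs of groups more. With an estimated correlation 5, 1, 1, 7 and 5 lists shifted, and with the block added as well 8, 0, 1, 4 and 7. Fry, which does not compare a list with other genes, called 17 lists for Aβ42 alone, 10 for AE1-329 alone and 20 for Aβ42 with AE1-329. Among genes above the median level AE1-329 alone shifted 3 lists and the correlation of the AE1-329 changes was 0.618 in place of 0.574. The slope was 0.835 with genes chosen in 2 litters. Unless named, the cause was not tested.

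With each array left out in turn, counts ran from 4210 to 5698 genes for Aβ42 alone, 1491 to 3093 for AE1-329 added to Aβ42, 1410 to 2345 for AE1-329 alone, 3507 to 5406 for Aβ42 with AE1-329 and 246 to 557 for the interaction, which moved by over 1.5 times without replicate 2 (246) or 3 (254) of Aβ42 alone or replicate 2 of AE1-329 alone (254). Lists ran from 10 to 11, 7 to 10, 3 to 8, 12 to 14 and 8 to 10, where AE1-329 alone shifted 8 without its replicate 2 and 3 without vehicle replicate 2. The slope ran from 0.821 to 0.863, the correlation from 0.518 to 0.573 and the overlap from 411 to 756 genes. The cause was not tested. Of the 333 named gene results, 305 passed and 293 of these passed under every alternative that gave them a value, where only genes above the median level gave 286 of the 333 and only the groups of a comparison also 286. After quantile normalization again the share of higher calls went from 54.3% to 50.8% for AE1-329 added to Aβ42 and from 53.0% to 49.5% for the interaction. A count of raised and lowered genes with genes chosen in 2 litters could not be formed, because the single litter left gives no test, and the share of genes with the opposite sign was given instead. The number of arrays limits small changes, since the simulated interaction of 1.5-fold was recovered for 152 of 200 genes, and the signal over background of single probe sets is unknown.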

Other observations

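All tests in this part were chosen only after the result was seen, except that of dimmer arrays of litter 3. Gene families outside the fixed lists were grouped by the stem of the symbol, and 319 families with at least 8 measured members were tested with camera in each comparison. None of the family calls given here held with an estimated correlation (adjusted p from 0.440 to 0.684). Of 8 Nop genes, which include snoRNP core proteins, 5 rose with Aβ42 alone (adjusted p = 0.0315), 5 fell when AE1-329 was added (mean -0.49, adjusted p = 1.06e-05) and 5 fell with AE1-329 alone (adjusted p = 0.00102). Of 10 Utp genes of the small-subunit processome, 5 rose, 8 fell and 6 fell (adjusted p = 0.0353, 1.06e-05 and 2.41e-04). With AE1-329 present 4 of 8 Nop and 6 of 10 Utp genes rose with Aβ42 and 1 of each fell (adjusted p = 0.203 and 0.111), and no interaction passed (0.152 and 0.774). Of 9 Exosc genes of the RNA exosome, 5 fell in each AE1-329 comparison (adjusted p = 0.00704 and 0.00799), and the family did not pass for Aβ42 alone (0.804).

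All 8 Bbs genes, of the BBSome and its chaperones, fell with Aβ42 alone (mean -0.40, adjusted p = 2.32e-04), and 4 rose with AE1-329 added (0.22, 5.89e-04) and 4 with AE1-329 alone (0.20, 0.00799). The directions given were kept with quantile normalization again.

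Genes of the choroid plexus, the epithelium that makes cerebrospinal fluid, differed between litters in every group. Of a list of 12 markers with 10 measured, none of them in another list here, 9 had their lowest value in litter 3 in all 4 groups and 7 their highest in litter 2, with transthyretin Ttr, brighter than 99.2% of genes, at 12.59, 12.84 and 11.89 in litters 1 to 3 and the list means at 7.95, 8.22 and 7.54. The endothelial and mural list was also lowest in litter 3 in all 4 groups (7.28, 7.29 and 7.10). Dimmer litter 3 arrays cannot be judged, as array medians are aligned, and 5.70% of genes were lowest there in all 4 groups (chance 1.23%). Carried-over choroid plexus cells are a candidate explanation, although isolation with CD11b beads would remove such cells, and how far microglia themselves express these genes was not tested. None of the 10 passed limma's test in any comparison, where their mean change lay between -0.09 and 0.07.

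Replicate 3 of AE1-329 alone stood apart in genes that Aβ42 raised, with 15 of its 16 genes at least 1 log2 unit above both other arrays, 7 of them in the type I interferon list. Mixed-in RNA or cells of Aβ42 cultures are argued against, because the median share needed, 27.5%, would raise the 341 genes that Aβ42 raised at least 2-fold by a median of 0.70, against 0.09 measured, and Cxcl2 by 5.17, against -0.09. A higher interferon level of litter 3 is argued against as the whole cause, because 0 of the 15 genes stood 1 log2 unit above both other litters in the vehicle cultures, although they were higher there by a median of 0.70, so a part may come from the litter. No biological explanation was tested.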
